A study of Mus musculus with 35 samples.

How the data were processed

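The deposited HTSeq count tables were used as given, 1 table for each of the 4 cell stages, and all 35 columns were used. Reads were aligned to mm10 with TopHat2 and counted with HTSeq, per the submitters' processing notes. Tool versions, the annotation, the counting mode and the strand setting are not given in the sources used here. The tables hold 23363 gene counts per library and 5 counters of reads that name no gene. These counters took 56.6 to 77.9% of the table totals, with 22.6 to 57.4% for no feature and 16.6 to 45.8% for reads placed more than once. The ribosomal precursor gene Rn45s took 0.37 to 15.7% of gene counts.

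Genes were placed on GRCm38 (mm10) by symbol, 20915 by the current symbol and 1888 by an older one, and 560 had no position. The receptor loci stand in the tables as whole-locus features (such as Igk, or Tcrbc1 for a Tcrb constant region), so the lists of receptor segments were matched to those features. Features named iEk, 3Ek, Ed and Eb were chosen as checks of the deletions after their names were seen. The gene Wls was in the fixed list of genes flanking Igk but lies on chromosome 3.

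Each stage was fitted with its 4 genotypes in edgeR 4.0.16 (R 4.3.3). Genes were kept by filterByExpr (minimum count 10, total count 15), libraries were scaled by TMM, and deletions were tested against the wild type with the robust quasi-likelihood F-test, 2-sided. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Comparisons between stages, and of deletion effects between stages, used fits of both tables joined by gene. The tested genes numbered 12580 in pre-B, 13940 in immature B, 13905 in DN and 13078 in DP cells, 14583 in DN with DP and 14322 in pre-B with immature B cells. The common biological coefficient of variation was 0.816, 0.602, 0.674, 0.682, 0.702 and 0.746 in the same order. SE is the absolute log2 fold change divided by the square root of F. Values are counts scaled to the TMM-adjusted library size (CPM), given as mean ± SD over libraries, with the deletion first and the wild type second unless named otherwise.

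Against a group with 0 counts a fold was computed from a floor of 3 counts over the group and given as a lower bound, and with 1 to 3 counts only the levels are given. Floors cover counting error only, and bootstrap intervals the spread between genes. Lists of genes were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists of a comparison. For each list the members called over all genes and the members called when adjusted over the list alone were counted. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

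The tests, the 35 lists, the alternatives and the rule for naming genes were chosen before the data were examined. Genes were named if they belong to a receptor locus or its flanking list, or were among the 10 largest changes in each direction at adjusted p under 0.05, mean log2 CPM of at least 1 and no overlap between the groups. Symbols of predicted genes were left out unless fewer than 5 genes remained, any called gene could be named where fewer than 20 were called, and up to 4 members with the smallest p were named for a list. Igl, Xist and the members of lists named without a call are outside that rule for some comparisons and were chosen after their values were seen.

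The alternatives were RLE in place of TMM, no low-count filter, replicate number as a block, the DESeq2 1.42.0 Wald test, only the groups compared in the fit, an estimated correlation for lists, and leaving out each library in turn. Where 1 library of a group was left, it was assumed to vary like the other groups. Leaving out the least correlated library of each table and a block with crossed replicate numbers were added after the data were seen. RLE moved the median log2 fold change of all genes by at most 0.0462 in any comparison.

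Whether replicate numbers pair libraries was checked with the correlation of gene residuals between libraries of the same number, before any blocked fit was compared. In DN cells all 3 wild-type and MiEk pairs had positive correlations (0.210, 0.223 and 0.209), so the paired fit is given beside that comparison. In groups of 2 the correlation of both pairs is the same number by construction, so the block is only an alternative there. The labels name no batch, and each stage is a table of its own. Replicates are not stated to be separate animals, so p-values measure the spread between these samples. Pearson r of log2 CPM between replicates of a group was 0.883 to 0.979. DN wild-type replicate 1 was the least like its group (0.896 to 0.919).

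The fits were tested on simulated data with the depth and spread of each table, with 50 genes changed at each of 4 sizes. Of 50 genes changed 2-fold, edgeR called 1 in pre-B, 4 in immature B, 11 in DN, 5 in DP, 2 in DN with DP and 1 in pre-B with immature B cells. At 4-fold it called 14, 39, 33, 31, 24 and 21, at 8-fold 37, 40, 40, 37, 34 and 35, and at 16-fold 41, 43, 47, 42, 42 and 39. None had the wrong sign. Among unchanged genes edgeR called 13, 12, 7, 19, 3 and 5 and DESeq2 called 81, 67, 65, 76, 70 and 74, so DESeq2 counts are given only as alternatives. These false calls were 12.3, 8.70, 5.07, 14.2, 2.86 and 4.95% of all edgeR calls, so the nominal 5% was passed in pre-B, immature B, DN and DP data. With 0 genes changed, 10 draws per table gave at most 6 calls in any comparison of pre-B or immature B cells, 2 in DN, 4 in DP and 2 in the joined tables. A planted list was found with both correlations in each fit, and 0 of 30 random lists were. The simulated genes varied independently, so this does not test the preset correlation on genes that vary together.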

Results

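Total RNA, depleted of ribosomal RNA, was sequenced from developing B and T lymphocytes of C57BL/6J mice aged 5 to 7 weeks. The 35 libraries form 16 groups, 4 sorted cell stages in each of 4 genotypes. Pre-B cells (CD19+IgD-B220+IgM-CD25+ckit-) and immature B cells (CD19+IgD-B220+IgM+) came from bone marrow. Double negative (DN) cells (CD4-CD8-, CD25+CD44-/+) and double positive (DP) cells (CD4+CD8+) came from thymus. The genotypes were wild type and mice lacking Eb, the enhancer of the T cell receptor beta locus (Tcrb), or MiEk or 3'Ek, the enhancers inside and downstream of the immunoglobulin kappa locus (Igk). Each group held 2 libraries except wild-type DN cells with 4 and MiEk-deleted DN cells with 3. Between 9511695 and 66172910 reads per library were assigned to genes. The sample titles give the deleted element and do not state whether 1 or both alleles were deleted.

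Igk lies at chr6:67555497-70726966 and Tcrb at chr6:40891229-41558452 (GRCm38/mm10), 25997045 bases apart, and the count tables held a single value for all Igk segments and 10 values for parts of Tcrb and its enhancer. A feature named iEk, after the intronic enhancer, had 0 counts in both MiEk-deleted pre-B libraries against 475 in the wild type, and 0 in MiEk-deleted immature B cells against 1170. The feature named 3Ek had 0 counts in 3'Ek-deleted pre-B cells against 182 in the wild type, and 0 against 355 in immature B cells. It had 1 count in MiEk-deleted pre-B cells too and 565 in MiEk-deleted immature B cells, so its absence in pre-B cells was not specific to the 3'Ek deletion. The feature named Eb had 0 counts in Eb-deleted DP cells and 19.9 ± 23.0 CPM in wild-type DP cells (SD, n = 2), and 1 count in Eb-deleted DN cells against 72 in the wild type. Transcripts of iEk and 3Ek had 0 counts in every DN and DP library, so the Igk deletions could not be checked in T lineage cells. The coordinates of these enhancer features are not given in the sources used here.

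The first question was what each enhancer deletion did in pre-B cells, the stage that rearranges Igk. In MiEk-deleted pre-B cells (n = 2 against 2, mean ± SD) Lima1, which encodes an actin-binding protein (chr15:99778470-99875456), rose (372 ± 80.5 against 6.81 ± 2.87 CPM, log2 fold change 5.77, SE 0.50, adjusted p = 0.00171). Reln, which encodes a secreted glycoprotein (chr5:21884454-22344702), fell (18.2 ± 5.62 against 457 ± 91.7 CPM, log2 fold change -4.65, SE 0.60, adjusted p = 0.0288). The transcript 4931429I11Rik was at 67.0 ± 4.35 CPM and at 0 in the wild type, at least 1874-fold higher (adjusted p = 0.0121). Igk transcripts averaged 167 ± 59.5 against 1420 ± 209 CPM (log2 fold change -3.09, SE 0.49), which did not pass the threshold (adjusted p = 0.130). The 3 genes named first were the only ones called among 12580 tested, 2 higher and 1 lower, and 267 genes had an unadjusted p under 0.05. Simulated pre-B data with 0 genes changed gave 0 to 4 calls in 10 draws. Without MiEk replicate 2 Reln had adjusted p = 0.0615 and 2 genes were called, and DESeq2 called 21. Igk was called in DESeq2 (adjusted p = 2.78e-11), without the low-count filter (2.39e-04), with only the compared groups in the fit (0.0122), with the replicate block (0.0272) and without pre-B Eb replicate 1 (2.86e-06), which shares the fit and without which 22 genes were called.

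Among fixed lists in MiEk-deleted pre-B cells, 17 of 25 immature and mature B cell genes were lower (camera adjusted p = 0.00381, adjusted p = 0.370 with an estimated correlation). Replication-dependent histone genes were lower in 56 of 61 (camera adjusted p = 5.01e-07, adjusted p = 0.781 with an estimated correlation). Ribosomal protein genes were lower in 67 of 74 (camera adjusted p = 4.94e-06, adjusted p = 0.825 with an estimated correlation). None of their members was called over all genes, and 0, 1 and 0 members were called when p was adjusted over the list alone. Lists of other kinds moved in the same comparison. Markers of dendritic cells were lower in 9 of 9 (camera adjusted p = 0.0114, adjusted p = 0.762 with an estimated correlation) and those of plasma cells in 6 of 6 (camera adjusted p = 0.0439, adjusted p = 0.499 with an estimated correlation). Sex-linked genes were higher in 4 of 6 (camera adjusted p = 0.00381, adjusted p = 0.370 with an estimated correlation), 4 of them called over the list alone, and Xist was at 0.654 CPM in MiEk replicate 2.

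In 3'Ek-deleted pre-B cells Igk transcripts averaged 515 ± 103 against 1420 ± 209 CPM (n = 2 and 2, log2 fold change -1.46, SE 0.47), which was not called (adjusted p = 1.00). The iEk feature was at 3.48 ± 2.82 against 5.67 ± 0.276 CPM and was not called either. The test called 0 genes in edgeR, with 278 at an unadjusted p under 0.05, against 20 in DESeq2, 2 without 3'Ek replicate 2 and 7 without Eb replicate 1. With the replicate block 3 genes were called. Of the interferon response list 15 of 19 members were lower (camera adjusted p = 3.8e-04, adjusted p = 0.391 with an estimated correlation), 0 of them called over all genes and 1 adjusted over the list alone. Markers of thymic epithelium and stroma were lower in 7 of 7 (camera adjusted p = 0.0224, adjusted p = 0.409 with an estimated correlation) and small nucleolar RNA genes higher in 48 of 78 (camera adjusted p = 0.0461, adjusted p = 0.409 with an estimated correlation), with 0 members called either way.

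The Igk enhancer deletions were also compared with each other in pre-B cells. Lima1 was higher in MiEk-deleted than in 3'Ek-deleted cells (372 ± 80.5 against 7.05 ± 1.39 CPM, log2 fold change 5.72, SE 0.50, adjusted p = 0.00185), and 4931429I11Rik averaged 67.0 ± 4.35 against 0.0437 CPM, the latter from 2 counts (adjusted p = 0.0299). These were the 2 genes called, with 197 at an unadjusted p under 0.05, against 0 to 6 in simulated data with 0 genes changed. Igk did not differ by the test (log2 fold change -1.63, SE 0.47, adjusted p = 1.00). Without pre-B Eb replicate 1 the count was 18, with Igk among them (adjusted p = 0.0291), and in DESeq2 it was 30, Igk again included (0.0196).

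Eb lies in a locus that is inactive in pre-B cells. With Eb deleted there, Igk transcripts averaged 1593 ± 479 against 1420 ± 209 CPM (log2 fold change 0.17, n = 2 and 2). The edgeR test called 0 genes, with 274 at an unadjusted p under 0.05, and DESeq2 called 5. Without Eb replicate 2 the count was 564 and without Eb replicate 1 it was 1. Eb replicate 1 and 2 were also the least alike of all groups (Pearson r across genes = 0.883).

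Immature B cells have assembled a light chain and carry IgM on their surface. In MiEk-deleted immature B cells (n = 2 against 2, mean ± SD) Igk transcripts fell (1157 ± 185 against 4520 ± 109 CPM, log2 fold change -1.97, SE 0.29, adjusted p = 0.0177). Reln fell here too (3.84 ± 1.20 against 123 ± 19.0 CPM, log2 fold change -5.00, SE 0.36, adjusted p = 2.92e-05), and so did the transcript A130040M12Rik (59.5 ± 1.89 against 1004 ± 78.0 CPM, log2 fold change -4.08, adjusted p = 2.92e-05). Trib2, which encodes a pseudokinase, rose (1060 ± 175 against 271 ± 6.53 CPM, log2 fold change 1.97, SE 0.27, adjusted p = 0.0105). The gene for the short-chain dehydrogenase Dhrs3 rose (60.1 ± 2.48 against 9.96 ± 5.73 CPM, log2 fold change 2.59, adjusted p = 0.0317). Of the Schlafen family, Slfn9 rose (2.18, adjusted p = 0.0317) and Slfn8 fell (-1.84, adjusted p = 0.0317). Lower transcripts further included Bhlhe40, a transcriptional repressor (-1.96, adjusted p = 0.0184), the histone gene Hist3h2ba (-2.45, adjusted p = 0.0105) and Lrrc32, at 0.162 against 10.1 ± 0.582 CPM. Plcd3 was at 0, at least 173-fold lower, and BC018473 was at 50.1 ± 18.5 CPM against 1 count in the wild type.

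Of 13940 genes tested in MiEk-deleted immature B cells, 15 were called, 5 higher and 10 lower, with 531 at an unadjusted p under 0.05. The count was 24 without wild-type replicate 2, 25 without MiEk replicate 1, 58 without MiEk replicate 2 and 66 in DESeq2. Igk lost its call without MiEk replicate 1 (adjusted p = 0.0741) and with only the compared groups in the fit (0.208, 4 genes called). Without wild-type replicate 1 the adjusted p was 0.0946 for Dhrs3, 0.134 for Slfn9, 0.0661 for Bhlhe40 and 0.0619 for Slfn8, and without wild-type replicate 2 it was 0.0583 for Slfn9. The iEk feature itself was called too (at 0 counts, at least 352-fold lower, adjusted p = 0.00154), except with only the compared groups in the fit (0.178). The remaining called genes were Gm6682 (5.11, adjusted p = 0.0260), not called without MiEk replicate 1 (adjusted p = 0.0688), and Gm13157 (-1.92, adjusted p = 0.0162).

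Transcripts of the lambda light chain locus Igl averaged 6270 ± 1300 against 2869 ± 1350 CPM in the same cells and were not called over all genes (log2 fold change 1.13, SE 0.38, adjusted p = 0.909). Of the immature and mature B cell genes 21 of 25 were lower (camera adjusted p = 3.4e-11, adjusted p = 0.662 with an estimated correlation). Cd22, an inhibitory coreceptor, averaged 225 ± 73.8 against 636 ± 144 CPM (log2 fold change -1.498, adjusted p = 0.191), and Cd83, Cd38 and Ciita had log2 fold changes of -1.09, -0.85 and -0.90. None of these was called over all genes, and 4 were when adjusted over the list alone. T cell markers were higher in 13 of 14 (camera adjusted p = 6.37e-04, adjusted p = 0.683 with an estimated correlation), and 13 of the 14 were highest of all immature B libraries in MiEk replicate 1, where Cd8a was at 22.7 CPM. The Tcrb constant regions Tcrbc1 and Tcrbc2 were high in that library too and were called only without MiEk replicate 2 (adjusted p = 0.0239 and 0.0244).

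In 3'Ek-deleted immature B cells Wls, which encodes a carrier of Wnt proteins, rose (190.3 ± 54.7 against 33.9 ± 9.15 CPM, log2 fold change 2.49, SE 0.33, adjusted p = 0.0303). It lies on another chromosome (chr3:159839672-159938664). Mtap7, a microtubule-associated protein gene, fell (16.1 ± 1.80 against 71.6 ± 9.09 CPM, log2 fold change -2.15, SE 0.30, adjusted p = 0.0416), and the 3Ek feature itself was at 0, at least 101-fold lower than 4.41 ± 0.305 CPM (adjusted p = 0.0303). Igk transcripts averaged 1294 ± 45.3 against 4520 ± 109 CPM (log2 fold change -1.81, SE 0.28) and missed the threshold (adjusted p = 0.0710). It passed without wild-type replicate 1 (0.0300), without the low-count filter (0.00101), with the replicate block (0.0463) and in DESeq2 (3.25e-13). The edgeR test called these 3 genes, 1 higher and 2 lower, with 912 at an unadjusted p under 0.05, against 0 to 5 in simulated data with 0 genes changed. The count was 20 without wild-type replicate 1, 17 without replicate 2, 8 without 3'Ek replicate 1, 2 without replicate 2 and 95 in DESeq2. Wls was not called without 3'Ek replicate 2 (adjusted p = 0.123). Without 3'Ek replicate 1 and 2 in turn, the 3Ek feature had adjusted p = 0.0584 and 0.0939 and Mtap7 0.184 and 0.123.

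Replication-dependent histone transcripts were lower in 58 of 62 members in 3'Ek-deleted immature B cells (camera adjusted p = 9.47e-25, adjusted p = 0.896 with an estimated correlation), for example Hist1h3h at 53.9 ± 5.19 against 172 ± 38.3 CPM (log2 fold change -1.68). None was called over all genes and 21 were adjusted over the list alone. Markers of myeloid cells were lower in 17 of 17 (camera adjusted p = 7.2e-04, adjusted p = 0.915 with an estimated correlation). Interferon response genes were lower in 17 of 20 (camera adjusted p = 4.63e-05, adjusted p = 0.896 with an estimated correlation), with 0 members called over all genes in either list and 0 and 1 adjusted over the list alone.

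Compared directly in immature B cells (n = 2 and 2), MiEk-deleted and 3'Ek-deleted libraries had Igk transcripts at 1157 ± 185 against 1294 ± 45.3 CPM, which did not differ by the test (log2 fold change -0.16, SE 0.28, adjusted p = 0.989). Reln (-5.33, adjusted p = 3.25e-05), Wls (-3.20, adjusted p = 0.00135), A130040M12Rik (-3.64, adjusted p = 4.08e-05) and Cntn2, a neural adhesion gene (-4.51, adjusted p = 0.00307), were lower in MiEk-deleted cells. Higher there were Slfn9 (2.95, adjusted p = 0.00307), Dhrs3 (3.13, adjusted p = 0.00904), the phosphatase gene Dusp7 (2.09, adjusted p = 0.0431) and the histone genes Hist4h4 (583 ± 157 against 105 ± 34.7 CPM, log2 fold change 2.47, SE 0.35, adjusted p = 0.0106) and Hist1h3h (1.69, adjusted p = 0.0307). Against a group at 0 counts, the 3Ek feature and BC018473 were at least 175-fold and 1149-fold higher, and iEk and Plcd3 at least 235-fold and 247-fold lower. In all, 16 genes were called, 8 each way, with 795 at an unadjusted p under 0.05. Without MiEk replicate 1 or 2 the count was 25 or 230, without wild-type replicate 1, which shares the fit, it was 62, and DESeq2 called 113. With RLE in place of TMM it was 21, 9 higher and 12 lower. Without 3'Ek replicate 1, 5 of these named genes lost their calls, with adjusted p = 0.0961 for Dhrs3, 0.0508 for Slfn9, 0.104 for Hist4h4, 0.289 for Dusp7 and 0.118 for Hist1h3h. Without 3'Ek replicate 2 it was 0.0667 for Dhrs3, 0.0820 for Dusp7 and 0.208 for Hist1h3h.

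With Eb deleted in immature B cells Igk averaged 6236 ± 140.1 against 4520 ± 109 CPM (log2 fold change 0.46, SE 0.28, adjusted p = 1.00). The test called 0 genes in edgeR and 0 in DESeq2, with 249 at an unadjusted p under 0.05, and 2 without wild-type replicate 1. Histone genes were lower in 56 of 62 (camera adjusted p = 1.36e-12, adjusted p = 0.713 with an estimated correlation). The pro-B and pre-B program was lower in 17 of 20 (camera adjusted p = 9.22e-09, adjusted p = 0.713 with an estimated correlation). Myeloid markers were higher in 17 of 17 (camera adjusted p = 3.5e-07, adjusted p = 0.713 with an estimated correlation). Adjusted over the list alone, 2, 0 and 0 members were called.

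**Figure D1:**
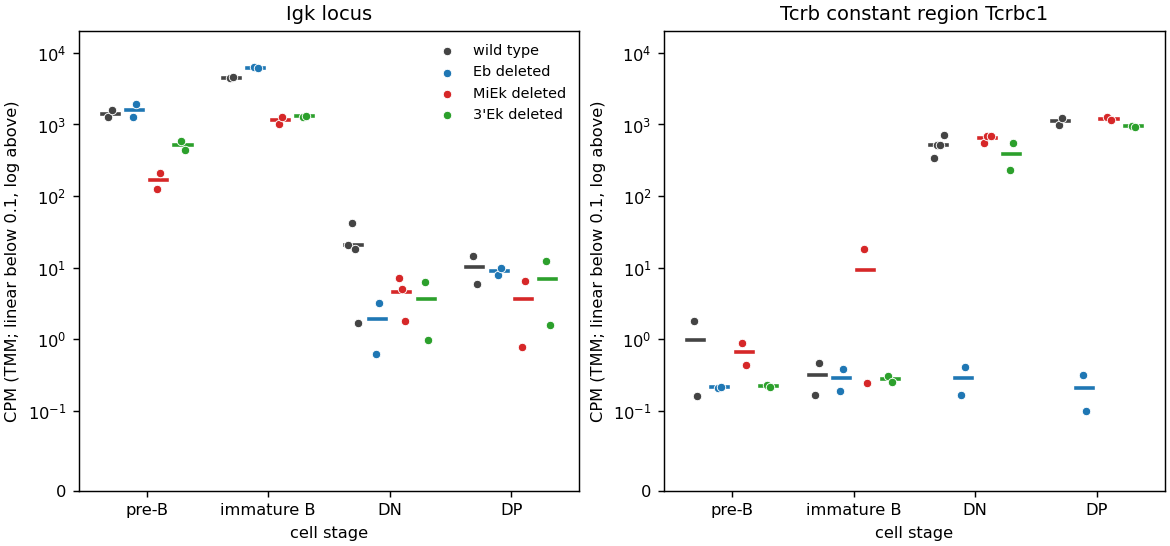
Transcripts of Igk and of the Tcrb constant region Tcrbc1 by cell stage and genotype, in CPM on an axis that is linear below 0.1 and logarithmic above, each point 1 library and each line the group mean. In pre-B and immature B cells Igk lay below the wild type in both Igk enhancer deletions, with a mean of 167 CPM in MiEk-deleted pre-B cells, and Tcrbc1 averaged 0.288 and 0.212 CPM in Eb-deleted DN and DP cells.

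DN cells rearrange Tcrb under the control of Eb. In Eb-deleted DN cells (n = 2 against 4, mean ± SD) the Tcrb constant regions fell to near 0, Tcrbc1 (0.288 ± 0.169 against 519.9 ± 149.6 CPM, log2 fold change -10.83, SE 0.64, adjusted p = 2.42e-07). Tcrbc2 fell as well (0.469 ± 0.106 against 833 ± 171 CPM, log2 fold change -10.79, SE 0.50, adjusted p = 1.35e-08). Transcripts of the variable segments fell too (Tcrbv, 69.5 ± 11.1 against 381 ± 31.8 CPM, log2 fold change -2.45, SE 0.25, adjusted p = 1.69e-04), and the region of the first D and J segments (Tcrbd1-j1) was at 0.0650 against 280 ± 113 CPM. Outside the locus Camk4, a calmodulin-dependent kinase gene, fell (3.65 ± 0.405 against 52.7 ± 22.3 CPM, log2 fold change -3.85, SE 0.44, adjusted p = 5.36e-04). Mpzl2, a cell adhesion gene, rose (315 ± 10.4 against 86.5 ± 15.6 CPM, log2 fold change 1.87, SE 0.22, adjusted p = 9.32e-04). The Notch target Dtx1 (661 ± 46.9 against 135 ± 65.7 CPM, log2 fold change 2.29, adjusted p = 0.0249) and the recombinase gene Rag1 (5184 ± 692 against 1974 ± 162 CPM, log2 fold change 1.39, adjusted p = 0.0334) rose. Higher interferon-induced genes were Ifi44 (50.9 ± 3.19 against 6.54 ± 2.85 CPM, log2 fold change 2.96, adjusted p = 0.0249), Ube2l6 (2.79, adjusted p = 0.0196) and Iigp1 (2.26, adjusted p = 0.0313). Also higher were the catenin gene Ctnnd1 (2.78, adjusted p = 0.0196) and the tetraspanin gene Cd82 (1.74, adjusted p = 0.0327).

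The count for Eb-deleted DN cells was 20 of 13905 genes, 12 higher and 8 lower, with 1174 at an unadjusted p under 0.05. Of the lower genes 7 were Tcrb features. Without wild-type replicate 1 the count was 83, without wild-type replicates 2, 3 and 4 in turn it was 8, 10 and 9, and without Eb replicate 1 it was 11. DESeq2 called 222, 78 higher and 144 lower. Mpzl2, Camk4, Tcrbc1, Tcrbc2, Tcrbv and Tcrbd1-j1 were called under each of the 6 single omissions. Dtx1, Ifi44, Rag1 and Cd82 lost their calls without any of wild-type replicates 2, 3 and 4 or either Eb replicate, with adjusted p of 0.0940 to 0.174, 0.0517 to 0.177, 0.0924 to 0.175 and 0.0747 to 0.193. The call was also lost by Ube2l6 without wild-type replicate 2 or 3 or either Eb replicate (0.0547 to 0.120), by Ctnnd1 without wild-type replicate 2 or 4 or either Eb replicate (0.0747 to 0.111), and by Iigp1 without wild-type replicate 2, 3 or 4 or Eb replicate 2 (0.0841 to 0.220).

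Interferon response genes were higher in 18 of 20 in Eb-deleted DN cells (camera adjusted p = 1.36e-13, adjusted p = 0.0261 with an estimated correlation), with 1 member called over all genes and 8 adjusted over the list alone. Stat1 had a log2 fold change of 1.03 (adjusted p = 0.0698). Genes of T cell receptor signalling and selection were lower in 17 of 22 (camera adjusted p = 3.88e-04, adjusted p = 0.0332 with an estimated correlation), 0 called over all genes and 3 over the list alone. Their members Klf2, Id3 and Nr4a1 had log2 fold changes of -3.39, -1.96 and -3.20. The early T cell program was higher in 16 of 23 (camera adjusted p = 1.6e-05, adjusted p = 0.160 with an estimated correlation), with 2 members called and 7 adjusted over the list alone. Cell cycle genes were lower in 30 of 31 (camera adjusted p = 4.84e-10, adjusted p = 0.117 with an estimated correlation), with 0 called over all genes and 1 adjusted over the list alone.

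MiEk lies in a locus that is inactive in T cells. In MiEk-deleted DN cells (n = 3 against 4, mean ± SD) Rps6kl1, a kinase-like gene, rose (69.1 ± 17.1 against 12.6 ± 0.907 CPM, log2 fold change 2.45, SE 0.28, adjusted p = 0.00319). Rasa4, a Ras GTPase-activating protein gene, rose (120 ± 44.6 against 6.24 ± 4.01 CPM, log2 fold change 4.27, adjusted p = 0.0456). Spib, which encodes a transcription factor of B and dendritic cells, rose (82.9 ± 32.1 against 24.5 ± 4.50 CPM, log2 fold change 1.76, adjusted p = 0.0351). Syne2 (1.95, adjusted p = 0.0261), Mtmr9 (1.75, adjusted p = 0.0261), Fam102b (1.67, adjusted p = 0.0261), Akap2 (1.501, adjusted p = 0.0261) and Emp1 (1.40, adjusted p = 0.0303) were higher too. BC018473 was at 163 ± 36.6 against 0.288 ± 0.323 CPM (adjusted p = 0.00740) and 2610109H07Rik at 29.3 CPM against 2 counts in the wild type. Hist3h2ba fell (8.95 ± 4.45 against 71.8 ± 37.9 CPM, log2 fold change -3, adjusted p = 0.0261).

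These were the 11 genes called in MiEk-deleted DN cells, 10 higher and 1 lower, of 13905 tested, with 502 at an unadjusted p under 0.05. The replicate numbers may pair the wild-type and MiEk libraries, by residual correlations of 0.209 to 0.223, though no label states pairs. With the pairs in the fit 5 genes were called, all higher, 4 of them shared (Rps6kl1, Spib, Akap2 and Emp1). The other 7 of the 11 lost their calls there, with adjusted p of 0.216 for BC018473, 0.268 for Rasa4 and Hist3h2ba, 0.108 for Syne2 and Mtmr9, 0.0554 for Fam102b and 0.409 for 2610109H07Rik. RLE gave 14, 11 higher and 3 lower, and DESeq2 gave 57. Without wild-type replicates 1 to 4 in turn the count was 29, 2, 1 and 2, and without MiEk replicates 1 and 2 it was 2 and 3. Rps6kl1 was called under each of the 7 single omissions and BC018473 under all but that of wild-type replicate 3 (adjusted p = 0.0574). Syne2, Spib, Fam102b, Akap2, Emp1 and Hist3h2ba lost their calls without any of wild-type replicates 2, 3 and 4 and MiEk replicates 1 and 2 (adjusted p = 0.0647 to 0.263, 0.131 to 0.334, 0.0574 to 0.263, 0.0574 to 0.162, 0.0842 to 0.263 and 0.0574 to 0.263). Rasa4 and Mtmr9 lost theirs without each of these and MiEk replicate 3 (0.108 to 0.185 and 0.0535 to 0.277), and 2610109H07Rik without each of the 4 wild-type replicates and MiEk replicates 1 and 2 (0.0585 to 0.165).

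In MiEk-deleted DN cells the cell cycle genes were lower in 31 of 31 (camera adjusted p = 1.03e-14, adjusted p = 0.163 with an estimated correlation), none called over all genes and 1 adjusted over the list alone. The DP thymocyte program and the small nucleolar RNA genes passed the list test only with the pairs in the fit (adjusted p = 0.0107 and 0.0117, against 0.141 and 0.502 without them, and 0.703 and 0.974 with an estimated correlation). The immediate-early genes and the myeloid markers passed only without the pairs (adjusted p = 0.0461 and 0.0135, against 0.530 for both with the pairs, and 0.790 and 0.714 with an estimated correlation), the former with the opposite sign in the paired fit.

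In 3'Ek-deleted DN cells (n = 2 against 4) Ctse, which encodes the protease cathepsin E, rose (203 ± 10.7 against 29.6 ± 5.43 CPM, log2 fold change 2.78, SE 0.32, adjusted p = 0.00250). Gm8580 rose (102 ± 29.5 against 2.96 ± 1.94 CPM, log2 fold change 5.11, adjusted p = 0.00425). Tmem108, a transmembrane protein gene, fell (1.76 ± 0.635 against 35.04 ± 11.9 CPM, log2 fold change -4.32, SE 0.50, adjusted p = 0.00250). No other gene was called, and 756 had an unadjusted p under 0.05. Without 3'Ek replicate 1 the count was 0 (adjusted p = 0.0833 for Ctse, 0.135 for Gm8580 and 0.141 for Tmem108). It was 7 without wild-type replicate 1, 5 without 3'Ek replicate 2 and 30 in DESeq2. Ribosomal protein genes were lower in 68 of 75 (camera adjusted p = 4.92e-08, adjusted p = 0.640 with an estimated correlation). Immediate-early genes were lower in 17 of 17 (camera adjusted p = 0.00296, adjusted p = 0.640 with an estimated correlation), with 0 members called over all genes and 0 and 0 adjusted over the list alone.

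DP cells express a rearranged Tcrb and undergo selection. In Eb-deleted DP cells (n = 2 against 2, mean ± SD) Tcrbc1 fell (0.212 ± 0.159 against 1115 ± 184 CPM, log2 fold change -12.07, SE 0.59, adjusted p = 4.33e-09). Tcrbc2 fell (1.52 ± 0.539 against 2440 ± 823 CPM, log2 fold change -10.71, adjusted p = 2.52e-08), and so did Tcrbv (4.49 ± 3.24 against 1506 ± 61.7 CPM, log2 fold change -8.44, SE 0.58, adjusted p = 2.49e-07). Next to the locus Ephb6, an ephrin receptor gene (chr6:41605482-41620509), fell (6.74 ± 1.61 against 259.5 ± 47.7 CPM, log2 fold change -5.28, SE 0.40, adjusted p = 7.67e-07). Mgam (chr6:40628831-40769123) was at 0, at least 135-fold lower than 9.92 ± 5.31 CPM (adjusted p = 0.0278). On other chromosomes Cd5, a receptor that limits T cell receptor signals, fell (12.6 ± 4.78 against 287 ± 48.6 CPM, log2 fold change -4.50, SE 0.39, adjusted p = 5.1e-06). Tox, a factor needed for selection to the CD4 lineage, fell (11.3 ± 1.00 against 132 ± 48.6 CPM, log2 fold change -3.55, SE 0.41, adjusted p = 1.72e-04). Nab2, a corepressor of early growth response factors, fell (2.77 ± 0.807 against 50.3 ± 5.23 CPM, log2 fold change -4.16, adjusted p = 1.82e-04). The adhesion receptor gene Cd2 fell (19.1 ± 2.08 against 169 ± 41.6 CPM, log2 fold change -3.14, adjusted p = 1.76e-04), and Cd6 fell (-1.64, adjusted p = 0.0426).

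Of the 22 genes called higher in Eb-deleted DP cells, 12 were called at least 2-fold higher in wild-type DN than DP cells. Among these Dtx1, a Notch target, rose (418 ± 147 against 15.2 ± 7.07 CPM, log2 fold change 4.79, SE 0.45, adjusted p = 1.46e-05). So did the interleukin 2 receptor gene Il2ra (199 ± 39.9 against 8.50 ± 0.300 CPM, log2 fold change 4.55, SE 0.53, adjusted p = 1.76e-04). The pre-T cell receptor gene Ptcra was higher (242 ± 94.9 against 21.3 ± 13.9 CPM, log2 fold change 3.51, adjusted p = 0.0332). The receptor genes Notch3 (309.6 ± 12.5 against 46.5 ± 0.359 CPM, log2 fold change 2.74, adjusted p = 1.82e-04) and Notch1 (807 ± 133 against 211 ± 20.2 CPM, log2 fold change 1.94, adjusted p = 0.0259) rose too. The sugar transporter gene Slc5a9 (127 ± 2.54 against 3.03 ± 0.0729 CPM, log2 fold change 5.38, adjusted p = 7.24e-05), Odz1 (3.49, adjusted p = 0.0119) and the peptidase gene Nln (4.25, adjusted p = 0.00220) also rose. Bst1, an ectoenzyme gene, averaged 25.8 ± 1.56 against 0.131 ± 0.0992 CPM (adjusted p = 0.0266). H19, a noncoding RNA, was at 47.7 ± 20.99 CPM against 1 count. Outside these 12, the sodium channel subunit gene Scn2b rose (3.38, adjusted p = 7.22e-04) and the globin gene Beta-s averaged 63.6 ± 10.1 against 0.131 ± 0.0992 CPM (adjusted p = 1.82e-04).

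Of 13078 genes tested in Eb-deleted DP cells, 44 were called, 22 each way, with 546 at an unadjusted p under 0.05. The count was 148 without wild-type replicate 1, 85 without 3'Ek replicate 1, which shares the fit, and 115 in DESeq2, 70 higher and 45 lower. Without wild-type replicate 2 and Eb replicates 1 and 2 in turn, adjusted p was 0.108, 0.488 and 0.264 for Bst1, 0.0834, 0.346 and 0.102 for Mgam and 0.106, 0.104 and 0.223 for Cd6. Notch1 was not called without wild-type replicate 2 (0.238), Ptcra and Odz1 without wild-type replicate 1 (0.0535 and 0.0544), or Nln without Eb replicate 1 (0.145). The other genes named for this comparison passed under each of the 4 single omissions.

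By list, genes of T cell receptor signalling and selection were lower in 19 of 22 in Eb-deleted DP cells (camera adjusted p = 9.17e-23, adjusted p = 0.00576 with an estimated correlation), 3 of them called over all genes and 8 adjusted over the list alone. The DP thymocyte program was lower in 19 of 23 (camera adjusted p = 8.98e-16, adjusted p = 0.0471 with an estimated correlation), 3 called and 7 over the list alone. The early T cell program was higher in 16 of 23 (camera adjusted p = 1.75e-08, adjusted p = 0.0261 with an estimated correlation), 5 called higher, and over the list alone 5 higher and 2 lower. Interferon response genes were higher in 19 of 20 (camera adjusted p = 4.86e-08, adjusted p = 0.0261 with an estimated correlation), 0 called over all genes and 2 adjusted over the list alone, for example Stat1 at 308 ± 44.0 against 137 ± 2.20 CPM (log2 fold change 1.17). Markers of myeloid cells were higher in 11 of 13 (camera adjusted p = 1.84e-06, adjusted p = 0.199 with an estimated correlation). B cell markers were higher in 9 of 10 (camera adjusted p = 0.00122, adjusted p = 0.287 with an estimated correlation), with 0 called over all genes and 1 and 1 adjusted over the list alone. Lyz2 was at 18.9 ± 0.295 against 1.04 ± 0.440 CPM and Cd79b at 52.9 ± 29.8 against 13.3 ± 4.85 CPM.

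**Figure D2:**
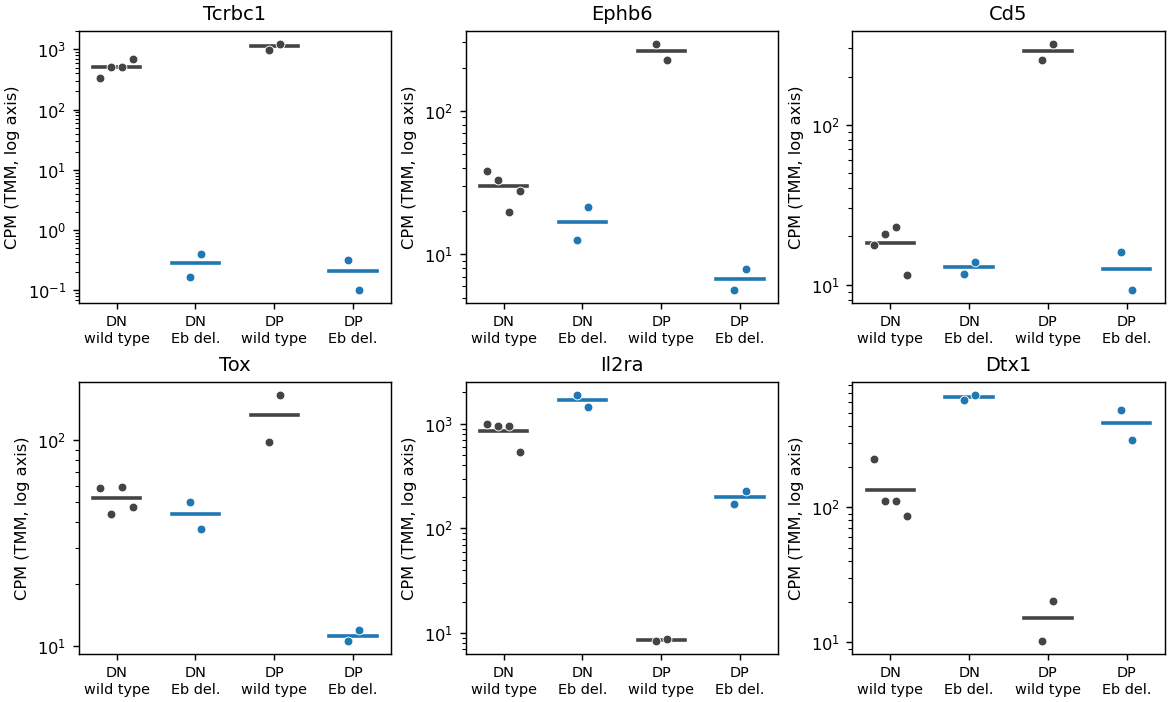
Transcripts of Tcrbc1, Ephb6, Cd5, Tox, Il2ra and Dtx1 in wild-type and Eb-deleted DN and DP cells, in CPM on a log axis, each point 1 library and each line the group mean. Cd5 averaged 12.6 CPM in Eb-deleted against 287 in wild-type DP cells, and Il2ra 199 against 8.50 CPM.

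In MiEk-deleted DP cells (n = 2 against 2) Aqp11, an aquaporin gene, fell (29.4 ± 2.31 against 304 ± 90.9 CPM, log2 fold change -3.37, SE 0.40, adjusted p = 0.00238). Cnn3, a calponin gene, fell (30.1 ± 5.26 against 183 ± 52.4 CPM, log2 fold change -2.60, SE 0.36, adjusted p = 0.0111). Tcrbc1 averaged 1209 ± 65.0 against 1115 ± 184 CPM (log2 fold change 0.12, adjusted p = 1.00). The edgeR test called those 2 genes, both lower, with 288 at an unadjusted p under 0.05, against 0 to 3 in simulated data with 0 genes changed. The count was 68 without wild-type replicate 1, 19 and 14 without MiEk replicates 1 and 2, 16 without 3'Ek replicate 1, which shares the fit, and 28 in DESeq2. Histone genes were lower in 55 of 59 (camera adjusted p = 1.03e-32, adjusted p = 0.645 with an estimated correlation). Ribosomal protein genes were lower in 72 of 73 (camera adjusted p = 4.38e-14, adjusted p = 0.821 with an estimated correlation), with 0 members called over all genes and 0 and 0 adjusted over the list alone.

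In 3'Ek-deleted DP cells the laminin gene Lama3 was at 45.2 ± 35.5 CPM and at 0 in the wild type, at least 774-fold higher (n = 2 and 2, adjusted p = 0.0143). It was not called without wild-type replicate 2 (0.141) or in DESeq2 (0.456), which called 47 other genes. It was the 1 gene called in edgeR, with 535 at an unadjusted p under 0.05, against 0 to 4 in simulated data with 0 genes changed. Without wild-type replicate 1 the count was 123, without wild-type replicate 2 it was 0, and without 3'Ek replicates 1 and 2 it was 11 and 238. Histone genes were lower in 53 of 59 (camera adjusted p = 1.59e-05, adjusted p = 0.873 with an estimated correlation), with 0 called over all genes and 0 adjusted over the list alone. They were lower in MiEk-deleted DP cells too, against the same wild-type libraries.

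Wild-type DP cells were compared with wild-type DN cells to give the normal step between these stages (n = 2 against 4, mean ± SD). The coreceptor genes that define the sort rose, Cd4 by the most (1581 ± 103 against 9.35 ± 7.92 CPM, log2 fold change 7.40, SE 0.96, adjusted p = 1.63e-04). Cd8a (1950 ± 281 against 23.8 ± 21.3 CPM, log2 fold change 6.36, SE 0.95, adjusted p = 5.47e-04) and Cd8b1 (6.21, adjusted p = 6.29e-06) rose too. Near Tcrb, Ephb6 rose (260 ± 47.9 against 29.7 ± 7.87 CPM, log2 fold change 3.13, SE 0.28, adjusted p = 6.63e-08), and in the Igk flank Rmnd5a rose (2360 ± 840.1 against 263 ± 25.9 CPM, log2 fold change 3.17, adjusted p = 4.9e-08). Called flanking genes went both ways. Arhgef5 (-3.27, adjusted p = 3.39e-05) and Mrps33 (-1.17, 0.0331) near Tcrb fell, as did Polr1a (-1.68, 4.09e-04) and Serbp1 (-1.32, 0.00348) near Igk. The survival gene Bcl2l1 rose (357 ± 41.4 against 33.1 ± 2.504 CPM, log2 fold change 3.43, adjusted p = 2.35e-09). Cd5 (3.97, adjusted p = 4.42e-09), the homing receptor gene Ccr9 (3.55, adjusted p = 5.46e-09) and the kinase genes Zap70 (2.60, adjusted p = 1.58e-06) and Itk (2.21, adjusted p = 2.35e-07) rose. Erg, a transcription factor gene, was at 0 in DP cells, at least 676-fold lower than 39.5 ± 12.6 CPM, Muc13 was at least 381-fold lower, and H19 was at 0.0303 against 235 ± 68.1 CPM. Il2ra (-6.67, adjusted p = 4.72e-08) and Notch3 (-3.01, adjusted p = 7.7e-06) fell. Il2ra encodes CD25, for which the DN cells were sorted, so the gate favours its direction. Tcrbv rose (1509 ± 62.4 against 378 ± 32.9 CPM, log2 fold change 1.998, adjusted p = 3.99e-05), while Tcrbd1-j1 fell (-5.35, adjusted p = 0.00404). Tcrbc1 rose (1117 ± 184 against 516 ± 149 CPM, log2 fold change 1.11, adjusted p = 0.0231), the latter not called without DN wild-type replicate 2 (0.0534) or DP wild-type replicate 2 (0.199). The Eb feature was higher (19.96 ± 23.1 against 0.520 ± 0.425 CPM, log2 fold change 5.26, adjusted p = 0.00643), except without DP wild-type replicate 1 (0.261).

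Between wild-type DP and DN cells 2075 of 14583 genes were called, 1024 higher and 1051 lower, with 3952 at an unadjusted p under 0.05 and a median log2 fold change over all genes of -0.11. Without DP wild-type replicate 2 the count was 1164, and with only these groups in the fit it was 1322. The DP thymocyte program was higher in 22 of 23 (camera adjusted p = 5.27e-48, adjusted p = 4.01e-05 with an estimated correlation), with 19 called and 21 adjusted over the list alone. The components of the T cell receptor complex were higher in 13 of 14 (camera adjusted p = 2.51e-07, adjusted p = 0.00839 with an estimated correlation), 7 called higher and 1 lower, and 9 and 1 adjusted over the list alone. T cell markers were higher in 13 of 14 (camera adjusted p = 8.96e-14, adjusted p = 0.00839 with an estimated correlation), 7 called higher and 1 lower, and 10 and 1 adjusted over the list alone. Myeloid markers were lower in 14 of 16 (camera adjusted p = 0.0200, adjusted p = 0.593 with an estimated correlation), 2 of them called, Lyz2 (-4.57, adjusted p = 7.6e-05) and Ngp (-5.64, adjusted p = 0.0433). Ngp lost its call without DN wild-type replicate 2 (0.0892) or 3 (0.0869) or DP wild-type replicate 1 (0.0609) or 2 (0.244). Markers of NK cells were lower in 7 of 12 (camera adjusted p = 0.469, adjusted p = 0.840 with an estimated correlation), with Nkg7 (-6.53, adjusted p = 2.56e-04) and Gzma (-3.05, adjusted p = 1.14e-04) called lower. Ribosomal protein genes were lower in 73 of 75 (camera adjusted p = 1.43e-14, adjusted p = 0.433 with an estimated correlation), 36 called over all genes and 48 adjusted over the list alone. The stages were counted in separate tables, so stage and any difference between tables cannot be separated.

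Whether Eb deletion acted differently in DP and DN cells was tested as the difference between the DP and DN effects. The DP effect was lower for Tcrbv (difference in log2 fold change -5.99, SE 0.49, adjusted p = 4.65e-07), Ephb6 (-4.47, adjusted p = 1.09e-05), Cd5 (-3.99, adjusted p = 4.72e-05) and Tox (-3.29, adjusted p = 0.00142). It was higher for Bst1 (6.08, adjusted p = 4.9e-04), Il2ra (3.59, adjusted p = 0.00852), the kinase gene Blk (4.92, adjusted p = 0.00829) and Ikzf3, a lymphoid transcription factor (3.07, adjusted p = 0.0353). Ikzf3 had 13202 counts over the Eb-deleted and 15366 over the wild-type DP libraries, before scaling to depth. Its difference therefore does not show a rise in DP cells. The test called 27 genes, 21 higher and 6 lower, with 908 at an unadjusted p under 0.05, and DESeq2 called 136. Genes abundant in DN cells, such as Bst1 and Il2ra, would also have a higher DP effect if DN cells lay inside the DP sort gate. Tcrbv, Ephb6, Cd5, Tox and Bst1 were called under each of the 10 single omissions. Without DN Eb replicates 1 and 2 adjusted p was 0.0697 and 0.0979 for Il2ra, 0.122 and 0.0595 for Blk and 0.0625 and 0.201 for Ikzf3, without DP wild-type replicate 2 it was 0.101, 0.101 and 0.288, and without DP Eb replicate 1 it was 0.0759 for Ikzf3. Without DP Eb replicate 2 it was 0.0520 for Il2ra and 0.127 for Ikzf3. The count was 155 without DP wild-type replicate 1, 18 without DP wild-type replicate 2 and 12 without DN Eb replicate 1. The list of T cell receptor signalling and selection genes was lower in 14 of 22, 3 called over all genes and 3 adjusted over the list alone (camera adjusted p = 2.46e-05, adjusted p = 0.0111 with an estimated correlation).

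The effect of MiEk deletion was not shown to differ between DP and DN cells. This test called 0 genes in edgeR, with 328 at an unadjusted p under 0.05, 11 in DESeq2, and 72, 3 and 1 without DP wild-type replicate 1, DN wild-type replicate 1 and DP MiEk replicate 2. Between immature B and pre-B cells the MiEk effect also gave 0 genes, with 277 at an unadjusted p under 0.05, 4 in DESeq2 and 13 without pre-B wild-type replicate 2. The 3'Ek effect gave 0, with 443 at an unadjusted p under 0.05, 19 in DESeq2, 12 without pre-B wild-type replicate 2, and 2 and 6 without pre-B 3'Ek replicates 1 and 2. The differences in the Igk log2 fold change between these B lineage stages were 1.14 for MiEk (SE 0.52, adjusted p = 1.000) and -0.30 for 3'Ek (SE 0.52, adjusted p = 1.00).

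Wild-type immature B cells were compared with wild-type pre-B cells as the normal B lineage step (n = 2 and 2, mean ± SD). Ms4a1, which encodes CD20, rose (4744 ± 1883 against 242 ± 97.8 CPM, log2 fold change 4.30, SE 0.49, adjusted p = 0.00132). The chemokine receptor gene Cxcr5 rose (153 ± 24.5 against 10.8 ± 2.60 CPM, log2 fold change 3.82, adjusted p = 0.00958). The antigen presentation gene H2-DMb2 rose (108 ± 19.6 against 7.08 ± 0.689 CPM, log2 fold change 3.93, adjusted p = 0.00132). Bank1 (3.91, adjusted p = 0.0157) and Btla (3.47, adjusted p = 0.00417) rose as well. The recombinase genes Rag1 (257 ± 155 against 3177 ± 641 CPM, log2 fold change -3.63, SE 0.53, adjusted p = 0.00520) and Rag2 (-3.20, adjusted p = 0.00958) fell. The survival gene Bcl2l1 fell (82.4 ± 14.1 against 470.2 ± 40.0 CPM, log2 fold change -2.51, adjusted p = 0.00417), with the interleukin 7 receptor gene Il7r (-2.15, adjusted p = 0.0365) and Il2ra (-1.84, adjusted p = 0.0384). Pre-B cells were sorted for CD25, which Il2ra encodes, so the gate favours the fall of Il2ra. Igk transcripts averaged 4345 ± 119.9 against 1496 ± 258 CPM and were not called (log2 fold change 1.54, SE 0.37, adjusted p = 0.0997) except in DESeq2 (4.53e-05) and without immature B wild-type replicate 1 and pre-B Eb replicate 1 together (0.00904).

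Of 14322 genes tested between these B lineage stages, 55 were called, 29 higher and 26 lower, with 1221 at an unadjusted p under 0.05. DESeq2 called 406, and with only these groups in the fit 17 were called, 14 higher and 3 lower. The count was 14 without immature B replicate 1, 12 higher and 2 lower, 93 without replicate 2, and 101 without pre-B replicate 2, 78 higher and 23 lower. The adjusted p of Cxcr5 was 0.0664 without immature B wild-type replicate 1 and 0.0856 without pre-B wild-type replicate 1 and 0.110 without pre-B wild-type replicate 2. For Bank1 it was 0.125 without immature B wild-type replicate 1 and 0.108 without pre-B wild-type replicate 1. Il7r had 0.494 without immature B wild-type replicate 1 and 0.0699 without pre-B wild-type replicate 2. Il2ra had 0.550 without immature B wild-type replicate 1 and 0.0856 without pre-B wild-type replicate 1. Bcl2l1 had 0.0587 without immature B wild-type replicate 1. Of the immature and mature B cell genes 21 of 25 were higher (camera adjusted p = 1.62e-12, adjusted p = 0.0568 with an estimated correlation), 2 called over all genes, and 11 higher and 1 lower adjusted over the list alone. The pro-B and pre-B program had 11 of 20 members lower, 4 called over all genes and 11 adjusted over the list alone (camera adjusted p = 2.24e-05, adjusted p = 0.233 with an estimated correlation). Its median log2 fold change was -0.62 and its mean 0.03, so the signs differ. Here too stage and count table cannot be separated.

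**Figure D3:**
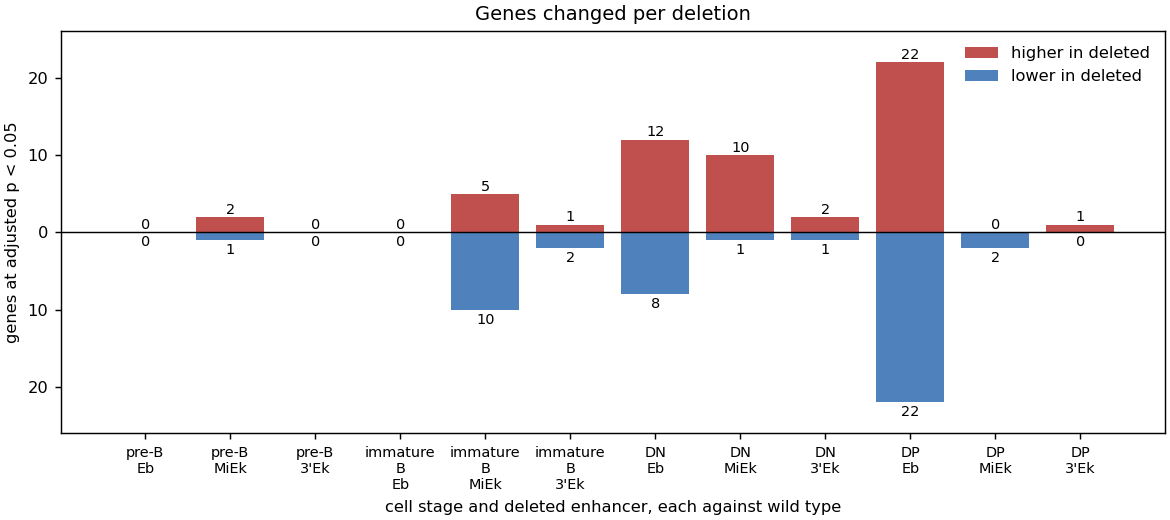
Number of genes called higher or lower than the wild type (edgeR adjusted p under 0.05) for each enhancer deletion in each cell stage. The bars run from 0 genes for Eb in pre-B and immature B cells and 3'Ek in pre-B cells to 22 in each direction for Eb in DP cells.

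Expression around the targeted loci was tested with the genes flanking them. In Eb-deleted DP cells 21 of 34 genes within 3 Mb of Tcrb were lower, 2 of them called, Ephb6 and Mgam (camera adjusted p = 0.00278, adjusted p = 0.212 with an estimated correlation). Of the named Tcrb flanking genes 7 of 12 were lower (camera adjusted p = 1.35e-05, adjusted p = 0.0471 with an estimated correlation), with 2 adjusted over the list alone. The test within 3 Mb of Tcrb was the 1 called among 60 tests of genes within 3 Mb of Igk, within 3 Mb of Tcrb or on all of chromosome 6, with 0 under the estimated correlation. Mgam was not called without wild-type replicate 2 (0.0834) or Eb replicate 1 (0.346) or 2 (0.102). Flanking genes of Igk had no called member in MiEk-deleted or 3'Ek-deleted cells of any stage except Wls in immature B cells, which is on chromosome 3. MiEk-deleted immature B cells had 23 of 45 genes within 3 Mb of Igk higher (camera adjusted p = 0.746), and 3'Ek-deleted immature B cells had 19 of 45 higher (camera adjusted p = 0.629).

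Over all comparisons, 166 of 577 tests of the other fixed lists passed, 77 higher and 89 lower, and 13 passed with an estimated correlation. Of those 13, 6 were the Tcrb features, T cell receptor signalling genes and interferon response genes in Eb-deleted DN and DP cells. The others were the DP program, early T cell program and Tcrb flanking genes in Eb-deleted DP cells, the DP program, T cell receptor complex and T cell markers between wild-type DP and DN cells, and T cell receptor signalling genes in the difference between the Eb effects. All deletions of a stage share its wild-type libraries, so a list that moves alike in several of them may reflect those libraries. This holds for histone genes in immature B and DP cells and for cell cycle genes in DN cells.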

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

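Of the tests in this part, those on chromosomal neighbours, on chromosome 6, on BC018473 and Hist3h2ba in both lineages, on an effect of the same size in all lineages, on genes called in T lineage libraries and on T cells in 1 library were chosen only after the result was seen. The effect of Eb deletion differed between DP and DN cells for 27 genes, by a test of the difference itself. The difference in log2 fold change, DP minus DN, was -5.99 for Tcrbv, -4.47 for Ephb6, -3.99 for Cd5, -3.37 for Nab2, -3.29 for Tox and -1.76 for Eif4e3. It was 18.04 for Dbn1, 11.65 for Cd163l1, 9.83 for Erg, 9.28 for H19, 8.74 for Muc13, 7.12 for Acot5, 6.95 for Itga9, 6.71 for Tubb3, 6.08 for Bst1 and 5.59 for Scin. Fitted values of genes with a group at or near 0 counts, such as Dbn1 and Cd163l1, do not measure the size of a change. Tcrbv, Ephb6, Cd5, Tox, Erg, H19, Muc13 and Bst1 were called under each of the 10 single omissions. Nab2 and Eif4e3 kept their calls, among single omissions, only in those of DN or DP wild-type replicate 1 (otherwise adjusted p = 0.0552 to 0.348 and 0.0725 to 0.314), and Cd163l1 and Tubb3 only in that of DN wild-type replicate 1 (otherwise 0.0708 to 0.326 and 0.0533 to 0.270). Without DN Eb replicate 1 or 2, DP wild-type replicate 2 or DP Eb replicate 1 both Dbn1 and Itga9 were lost, Dbn1 also without DN wild-type replicate 2 or 4 (0.0513 to 0.270) and Itga9 also without DN wild-type replicate 4 or DP Eb replicate 2 (0.0564 to 0.393). Scin was lost without DN Eb replicate 1 (0.0922) or DP wild-type replicate 2 (0.0807), and Acot5 without DN Eb replicate 1 (0.0625). Dixon's ratio, which has little power with 4 libraries, passed its limit for 0 of 33 named genes among wild-type DN libraries. The largest ratios were just below it, both from replicate 1, 0.8288 for Dtx1 (232.5 CPM against 86.6 to 112) and 0.812 for Hist3h2ba (128 against 43.3 to 59.2). Rasa4 was at 0.547 CPM in that replicate against 6.89 to 9.91.

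The early T cell genes that rose in Eb-deleted DP cells could come from DN cells inside the DP sort gate. The 50 most abundant DN-specific genes implied a median share of DN cells of 9.87% (bootstrap 95% interval 6.36 to 13.6), while 12 DN-specific genes called higher needed 61.7% (24.3 to 91.4). Of the 50 abundant genes 0 were lower in Eb-deleted than in wild-type DP cells. Of the 12, H19, Il2ra and Bst1 needed 6.34, 11.4 and 11.9%, about the share of the abundant genes, so DN cells stay open for these 3. Their Eb effect was also called higher in DP than in DN cells. So was that of Scin and Gm5111, which needed 5.64 and 3.03%. Erg, Muc13 and Cd163l1, called in the same direction, had 0 counts in wild-type DP cells. They were called lower there than in wild-type DN cells. DN cells stay open for all these calls. DN cells bring all their abundant transcripts, so DN cells alone would give both sets a like share. The 50 had a wild-type log2 fold change, DP against DN, under -3, while the 12 were only at least 2-fold lower in DP cells. The sets were thus chosen by unlike limits, and the gap does not decide whether DN cells are the whole cause. Some of the 12 are among the 50. The 12 were called higher in these same libraries, which raises the share they need, so DN cells as the whole cause are not excluded. A smaller share stays open. Myeloid and B cell markers and the globin gene Beta-s (63.6 against 0.131 CPM) were higher in the same libraries as well, which leaves a lower purity of the DP sort open. A block in development of cells without a Tcrb chain, which stay closer to the DN state, is a biological explanation that was not tested further.

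The effect of MiEk deletion averaged over the 4 stages called 62 genes, 31 each way, against 37 for 3'Ek and 15 for Eb. Such an average can be carried by some of the stages, so it does not show a change in each. The direction was the same in all 4 stages for 54 of the 62 MiEk genes, 29 of the 37 for 3'Ek and 3 of the 15 for Eb. Calling genes by the average itself favours such agreement. Examples were BC018473 (average log2 fold change 9.37), Hist3h2ba (-3.05), Slfn8 (-1.44), Pop4 (-1.13) and Nnt (-0.85), which had no position here. Spread along chromosome 6 from the deleted element is argued against for the set as a whole, since 2 of the 60 positioned genes lay there. The 95% range of random draws was 0 to 7, so an effect on a few genes there would not be seen. Segments of another strain, not limited to the chromosome of the deletion, are a candidate explanation. Of the 60, 31 had another called gene within 5 Mb, against a median of 17 in 10000 random draws (95% range up to 26, 17 draws as large). The numbers for 3'Ek (10 of 37) and Eb (0 of 12) were within random draws. With 2 of the 60 on chromosome 6, a segment linked to the deleted element would not account for most of them. The draws took genes singly, so neighbours that vary together for another reason would raise the number too.

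MiEk deletion called 19 genes in B lineage libraries, averaged over their 2 stages, and 16 of them were tested in T lineage libraries. An effect of MiEk in B lineage cells only for BC018473 and Hist3h2ba is argued against. These 2 were called in T lineage libraries as well in the same direction (log2 fold change 10.02 in B and 8.75 in T lineage for BC018473, -3.27 and -2.81 for Hist3h2ba, adjusted p = 0.0226 in T lineage for both), against 0.0187 genes by random overlap. That fit has no pairs. With the pairs in the DN fit neither was called, with similar log2 fold changes and larger errors (BC018473 9.22 with SE 0.98 before and 10.23 with SE 1.30 after, adjusted p = 0.216, and Hist3h2ba -3 with SE 0.47 before and -3.10 with SE 0.59 after, 0.268). The pairs also leave fewer degrees of freedom, and why the calls were lost was not tested. The other 14 were chosen as called in B and not called in T lineage libraries. Their signed median in T lineage cells was -0.18 (bootstrap 95% interval -0.795 to 0.483), against a median size of 2.58 in B lineage cells. The choice itself favours such a gap, so the medians do not decide whether the effect was of the same size in all lineages. In a test of B minus T lineage effect 6 of the 14 differed over all genes, A130040M12Rik (-3.87, adjusted p = 2.38e-06), Trib2 (2.505, 4.39e-05), Reln (-6.17, 1.61e-04), Dhrs3 (2.87, 5.84e-04), Dgke (2.04, 7.47e-04) and Gm13157 (-1.78, 0.0130). For these 6 an effect of the same size is argued against. Igk, Gm6682, 1700049G17Rik and Pold1 did not differ even when adjusted over the 16 genes alone (adjusted p = 0.520, 0.369, 0.394 and 0.0631). For the 14 an effect in B lineage cells only cannot be told apart from a smaller one in T lineage cells. The median log2 fold change of all 16 in T lineage cells, signed by the B lineage direction, was 0.138 (bootstrap 95% interval -0.522 to 1.28), and 8 of the 16 kept their direction. The rule that reads this value was changed after the value was seen, from taking a median near 0 as support to leaving it open when members go both ways. For 3'Ek the same median was 0.414 (0.267 to 0.954), with 12 of 15 genes in the same direction and 0 called in both lineages. The 12 were 11 of 11 lower and 1 of 4 higher genes, so a lean to lower values in T lineage libraries would give the same. In reverse, 10 of 16 genes called in T lineage libraries kept their direction in B lineage for MiEk (median 0.448, -1.07 to 3.27) and 9 of 10 for 3'Ek (0.923, 0.550 to 1.98). The genetic background of the deletion is tied to the deletion itself in these samples, so which of the 2 acted cannot be separated.

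T cell transcripts in MiEk-deleted immature B cells may come from T cells or their RNA in 1 library. Of 14 T cell markers fixed beforehand, 13 were highest in MiEk replicate 1 of the 8 immature B libraries, with Cd8a at 22.7 CPM against a median of 0.602 in the 6 libraries of other genotypes. A rise caused by the deletion is argued against, since 1 of the 14 was higher in MiEk replicate 2 than in those 6 libraries. The sort for CD19, B220 and IgM would remove T cells, and the source of the transcripts was not tested further.

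The count of genes changed in MiEk-deleted DN cells was compared with other splits of the same 7 libraries into 4 and 3. Of 35 splits 1, the real one, gave as many genes (11, highest other 1). The numbers may pair these libraries, so the real split is to be read against the 8 splits that part all 3 pairs, where the highest other was 0. The other 27 splits keep at least 1 pair together. The 8 are too few for a share under 0.05, and the paired fit called 5 genes.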

How the results depend on the processing

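Of the tests in this part, leaving out the least correlated library of each table (pre-B Eb 1, immature B wild type 1, DN wild type 1, DP 3'Ek 1), the block with crossed numbers and the simulated data with 0 genes changed were chosen only after the result was seen. Of 416 values of named genes, 0 changed direction under any alternative with a call before or after. Changes of direction among values called in neither fit were not counted. RLE kept the side of the threshold for 415, no filter for 402, DESeq2 for 397 of 408, the omission of the least correlated library for 399 and the replicate block for 387. With only the compared groups in the fit, where fewer samples inform the spread, 74 of 345 lost their call. Single omissions kept 2052 of 2360, with 300 calls lost and 8 gained. Except where a construction is named, the cause was not tested.

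Counts of called genes moved more. Without the low-count filter, which tests more genes, they were 10, 52 and 23 in pre-B cells (Eb, MiEk and 3'Ek, against 0, 3 and 0), 29, 96 and 331 in immature B (0, 15 and 3), 35 for Eb and 5 for 3'Ek in DN (20 and 3), 124, 44 and 34 in DP (44, 2 and 1), and 22 and 324 for MiEk against 3'Ek in pre-B and immature B (2 and 16). Without the filter the stage differences gave 63 for Eb in T cells (27), 8 for MiEk in T cells, and 19 and 60 for MiEk and 3'Ek in B cells (0 each), and immature B against pre-B gave 339 (55). DESeq2, in the same order, gave 5, 21 and 20 in pre-B, 66 and 95 for MiEk and 3'Ek in immature B, 222, 57 and 30 in DN (MiEk 11 in edgeR), 115, 28 and 47 in DP, 30 and 113 between the Igk deletions, 136, 11, 4 and 19 for the stage differences, and 406 for immature B against pre-B.

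Without the least correlated library the counts were 1, 22 and 7 in pre-B, 2 for Eb and 20 for 3'Ek in immature B, 83, 29 and 7 in DN, 85, 16 and 11 in DP, 18 and 62 between the Igk deletions, 64, 6 and 1 for the stage differences of Eb and MiEk in T cells and MiEk in B cells, and 102 for immature B against pre-B. With only the groups compared they were 9 and 1 for MiEk and 3'Ek in pre-B, 4 and 5 in immature B, 8 and 5 for Eb and MiEk in DN, 67, 6 and 2 in DP, 6 between the Igk deletions in pre-B, 1322 for DP against DN (2075) and 17 for immature B against pre-B. The replicate block gave 9 and 3 for MiEk and 3'Ek in pre-B, 5 between them, 9 for 3'Ek in immature B, 5 for MiEk in DN, and 7 and 3 for MiEk and 3'Ek in DP. The crossed block gave 35 for MiEk against 3'Ek in immature B, where the residuals of libraries with the same number had r = -0.228, and its 35 held all 16. A library was most like one with its own number in 8 of 8 cases in pre-B, 6 of 8 in immature B, 8 of 11 in DN and 8 of 8 in DP.

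Leaving out 1 library of the groups compared gave 0 to 564, 2 to 4 and 0 to 2 in pre-B (Eb, MiEk, 3'Ek), 0 to 2, 14 to 58 and 2 to 20 in immature B, 8 to 83, 1 to 29 and 0 to 7 in DN, and 32 to 148, 3 to 68 and 0 to 238 in DP. MiEk against 3'Ek in immature B gave 15 to 230, DP against DN 1164 to 2450, and immature B against pre-B 14 to 101. The stage differences gave 12 to 155 for Eb and 0 to 72 for MiEk in T cells, and 0 to 13 for MiEk and 0 to 12 for 3'Ek in B cells. Of 577 list tests 166 passed, and 13 with an estimated correlation, 156 with the block and 165 with RLE. Neighbourhoods of the loci passed 1 of 60 tests and 0 with an estimated correlation. The immediate-early genes in MiEk-deleted DN cells reversed with the block (adjusted p = 0.530). Lists were not refitted without single libraries, and the stage differences have no fit with only the groups compared. Depth and spread limit what is called: at 2-fold the simulated pre-B data gave 1 of 50 changed genes. With 0 genes changed, simulated data gave as many calls as the real ones or more for Eb, MiEk, 3'Ek and the Igk deletions against each other in pre-B (up to 6, 4, 3 and 6 against 0, 3, 0 and 2), Eb and 3'Ek in immature B (1 and 5 against 0 and 3), MiEk and 3'Ek in DP (3 and 4 against 2 and 1), and the stage differences of MiEk in T cells and of MiEk and 3'Ek in B cells (1, 0 and 1 against 0 each).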

Other observations

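No test in this part was run. Xist was at 0.654, 2.04 and 1.60 CPM in MiEk replicate 2 of pre-B, DN and DP cells. In each of the other 32 libraries it was at 168 CPM or more, including 456 in MiEk replicate 2 of immature B cells. The sex-linked gene Ddx3y was at 131.9, 128 and 199.7 CPM in MiEk replicate 2 of pre-B, DN and DP cells. In every library, also those with high Xist, Ddx3y was at 8.15 CPM or more. The sex of the animals is not given in the sources used here.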
